A study of Mus musculus with 6 samples.

How the data were processed

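RNA was measured in 6 whole testes of E16.5 mice, 3 labelled cKO and 3 labelled WT. Per the labels' protocols, total RNA was treated with DNase, polyadenylated RNA was isolated with oligo-dT beads and fragmented, and the libraries were sequenced on an Illumina NovaSeq. HISAT2 2.0.5 and the genome build GRCm38 are named in the submitters' processing notes. The counting tool, its strand setting, the annotation release and any trimming are not given in the sources used here. The deposited tables nevertheless carry gene identifiers of the C57BL/6NJ strain annotation: 41096 of 42747 rows have such an identifier, 145 rows lie on scaffolds of that assembly, and the remaining rows include 1651 predicted loci with no gene name. Of 29619 symbols shared with the GRCm38 annotation GENCODE M21, 0 had the same start, and the last gene on chromosome 1 ended at 208807027 in the file against 195323493 in GENCODE M21. Coordinates are therefore those of the files, in the C57BL/6NJ assembly, and were not mixed with GRCm38. The table held 0 rows on chromosome Y and 0 on the mitochondrial genome, so Y-linked and mitochondrial transcripts were not analysed here.

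The deposited counts are whole numbers of reads or fragments per gene, not normalised. The deposited FPKM values, per the file headers, are given per library and as group means. In each library FPKM equalled the count divided by gene length and by a library denominator that was 0.968 to 1.05 times the count total, within 0.0135 of edgeR's TMM factor over all rows, so the authors' FPKM already held a composition factor of that kind. A second FPKM table held identical values, and the deposited group means equalled the mean of the 3 libraries. Gene-level counts limit what can be said of genes that share reads: overlapping genes on opposite strands (Notum and Notumos) and near-identical copies (alpha globins) cannot be separated.

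From the counts, library totals, CPM and all tests were computed in R 4.3.3. Genes passing edgeR's filterByExpr (18383) were fitted with edgeR 4.0.16 (TMM scaling, glmQLFit and glmQLFTest, no covariate), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes are the absolute value divided by the square root of F, and 95% intervals use the fitted degrees of freedom. CPM used TMM-scaled library totals. The biological coefficient of variation was 19.7%. Totals of 15092619 to 17431546 counts gave tested genes a median of 282 to 329 counts per library. Counting error is then small beside the spread between animals except in rare genes, and no interval here covers anything but the fitted spread.

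Before the data were examined, 28 gene lists with 513 symbols were fixed from general knowledge of fetal testis cell types and of pathways tied to CK1α. Of these symbols 476 were matched in the files, 3 of them through a synonym in the RefSeq gene table, which was used for names only. The lists of Y-linked genes with Xist and of mitochondrially encoded genes had too few tested members (0 Y-linked and 1 mitochondrial symbol matched, and Xist was not called, log2 fold change -0.49, edgeR adjusted p = 0.664), which left 26 lists of at least 3. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 26 lists, and again with an estimated correlation and with fry. The naming rule was also fixed in advance. It took Csnk1a1, the 10 protein-coding genes with the largest rise and the 10 with the largest fall (called, no overlap between groups, mean of at least 2 CPM), up to 4 members of each list with the smallest p, the 2 most abundant members of each cell type list, and the 10 genes with the smallest adjusted p. Genes named outside it are marked as such, and some genes that it takes are not reported here.

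The procedure was tested on simulated data with the real means, depths and dispersions of the cKO against WT comparison (18383 genes, 200 of them changed). It recovered 51% of genes changed by 1 and 81% of genes changed by 2 on the log2 scale, called 12 unchanged genes among 144 calls, found the moved list and called 0 unchanged lists. Simulated genes were drawn independently of each other. The list results of the simulation therefore do not check the preset correlation used with camera, nor false list calls where genes of a list move together. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom 12.2 to 37.4 between libraries of 1 group), so no pair of libraries matched within that noise and each was counted as 1 replicate. The alternatives, listed before the data were examined, were DESeq2 size factors, upper-quartile factors or library totals alone in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1), no low-count filter beyond 1 count in all libraries together, a mean of at least 1 CPM, protein-coding genes only, the replicate number as a block, and leaving out each library in turn.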

Results

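Polyadenylated RNA of whole E16.5 mouse testes was sequenced in 6 libraries, 3 labelled cKO and 3 labelled WT, each from a separate mouse per the series design. The series title names CK1α, the serine/threonine kinase casein kinase 1 alpha encoded by Csnk1a1, in Sertoli cells, the supporting cells of the testis cords, so Csnk1a1 was taken as the targeted gene and cKO was read as a conditional knockout. The question was which transcripts of the fetal testis differ when CK1α is removed from Sertoli cells. Gene counts summed to 15092619, 15643263 and 17431546 in cKO libraries 1, 2 and 3 and to 15513157, 15281569 and 16646569 in WT libraries 1, 2 and 3. Values below are CPM, counts scaled to a common library total, as mean ± SD over the 3 libraries of a group. Log2 fold changes are cKO against WT. The p-values of single genes set a difference against the spread between these animals. Those of camera compare a list with the other tested genes and, unless stated otherwise, depend on the preset correlation between genes. Genes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and gene lists fixed before the data were examined with camera.

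Csnk1a1 itself was not lower in the libraries labelled cKO. Its level was 393 ± 14.1 CPM in cKO and 372 ± 24.0 CPM in WT, and single cKO libraries held 396, 405 and 377 CPM against 371, 396 and 348 CPM in WT. The log2 fold change was 0.08 (SE 0.117, 95% confidence interval -0.18 to 0.34; edgeR adjusted p = 0.798). The gene spans positions 63117222 to 63152689 on chromosome 18, plus strand, in the C57BL/6NJ coordinates of the files. Its count covers the whole gene in a whole organ, and the deleted part is not given in the sources used here, so it does not check the labels. None of the 6 CK1 family kinases on the list was called by edgeR, DESeq2 or limma-voom (1 at an unadjusted p under 0.05, and 1 lower adjusted over the list alone; camera adjusted p = 0.931). The median of this list was 0.06 and its mean -0.02. Csnk1g1 (log2 fold change -0.39, SE 0.12, edgeR adjusted p = 0.123) and Csnk1e (0.22, edgeR adjusted p = 0.343) lay nearest to a call.

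In cKO testes, 9 of 19 tested Wnt/β-catenin target genes and 12 of 26 p53 target genes were higher and 22 of 27 Sertoli cell markers were lower by edgeR. As lists these were called by camera with its preset correlation, and not with an estimated correlation (adjusted p = 0.145, 0.145 and 0.195 with an estimated correlation). Of 18383 genes tested, 276 were higher and 339 lower in cKO at an adjusted p under 0.05, and 328 of these 615 differed at least 2-fold (142 higher, 186 lower). The 3 cKO values lay apart from the 3 WT values for all 615 called genes, and for 21.6% of all tested genes, where chance gives 10%. Among protein-coding genes with a mean of at least 2 CPM, the largest rise was that of Sp5, a transcription factor gene activated by Wnt signalling, from 1.92 ± 0.576 to 90.2 ± 12.2 CPM (47.0-fold, log2 fold change 5.55, SE 0.219, edgeR adjusted p = 7.17e-07). Cdkn1a, which encodes the cell cycle inhibitor p21, followed at 18.2-fold, then the potassium channel subunit gene Kcng1 at 15.6-fold and Notum, a secreted Wnt inhibitor, at 13.3-fold. Ano3, Wnt7b, Cited4, Gpr55, Wif1 and Rnf43 completed the 10 largest rises, at 7.31 to 13.1-fold. The falls were led by neighbouring serpin genes on chromosome 12. Serpina3a had counts in 1 of the 3 cKO libraries (0.288 CPM there) against 9.72 ± 2.39 CPM in WT, and Serpina5 went from 52.3 ± 15.2 CPM in WT to 1.11 ± 0.942 CPM in cKO. Sel1l3 was 11.7-fold lower (134 ± 24.2 to 11.5 ± 0.376 CPM, log2 fold change -3.54, SE 0.161, edgeR adjusted p = 1.7e-06), and Hsd17b3, the enzyme that turns androstenedione into testosterone, was 9.94-fold lower. 3110035E14Rik, Pnmt, Fshr (the receptor of follicle-stimulating hormone), AF529169, Etd and Mafa made up the rest of the 10 largest falls, at 8.2 to 18.8-fold. Mybpc3, which encodes a cardiac myosin-binding protein, was 5.32-fold lower and was among the 10 genes with the smallest adjusted p. The number of calls depended on single libraries. It was 134 higher and 170 lower without cKO library 3, 105 and 218 without WT library 1, 180 and 190 without WT library 2, and 105 and 167 without WT library 3. Without cKO library 1 it rose to 316 higher and 399 lower, and without cKO library 2 to 342 and 381.

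**Figure D1:**
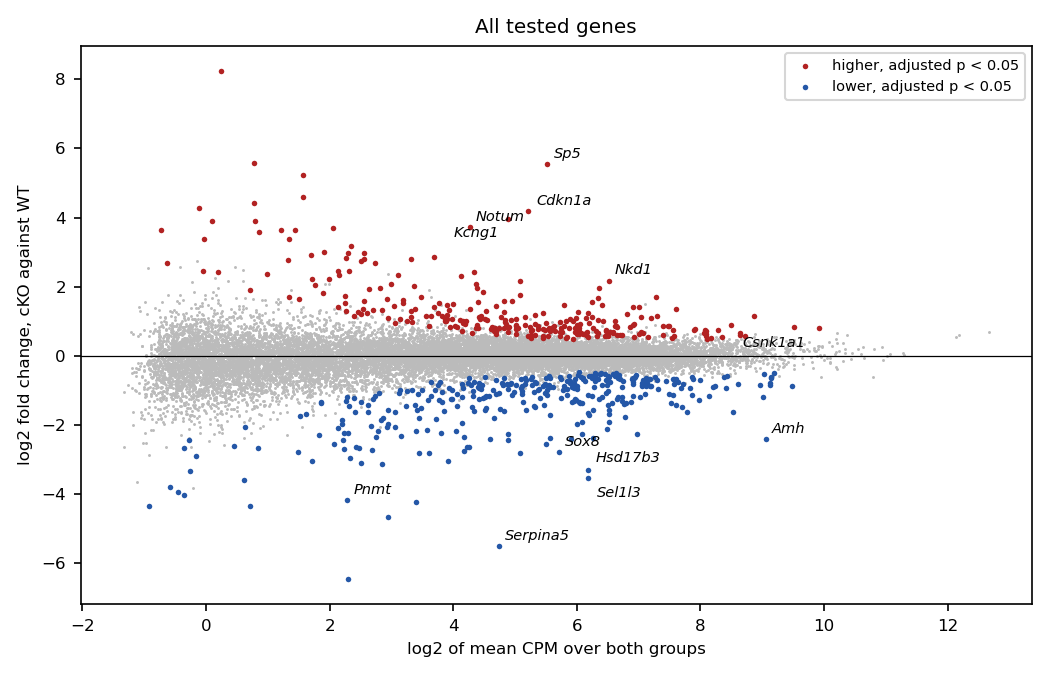
Log2 fold change of cKO against WT (vertical axis) against the log2 of mean CPM over both groups (horizontal axis) for the 18383 tested genes, 1 point per gene. Red points are the 276 genes higher and blue points the 339 genes lower in cKO by edgeR, gray points were not called, and Csnk1a1 lies at 0.08.

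Wnt/β-catenin target genes were higher in part. Of 19 tested, 9 were higher in cKO and none was lower by edgeR, DESeq2 or limma-voom (10 higher and 0 lower at an unadjusted p under 0.05, and 10 higher adjusted over the list alone). The list had a median of 0.64 and camera adjusted p = 4.66e-10 (adjusted p = 0.145 with an estimated correlation). Besides Sp5 and Notum, the feedback inhibitor Nkd1 rose from 33.2 ± 1.67 to 150 ± 14.9 CPM (log2 fold change 2.17, SE 0.124, edgeR adjusted p = 6.73e-06) and Axin2, a scaffold of the β-catenin destruction complex, from 45.1 ± 0.831 to 125 ± 15.2 CPM (1.47, SE 0.124, edgeR adjusted p = 0.000127). Rnf43, a ubiquitin ligase that removes Wnt receptors, and Wif1, a secreted Wnt inhibitor, rose by 2.87 and 2.96 on the log2 scale. The 21 β-catenin pathway components, which include receptors and the destruction complex, held no gene called by edgeR or limma-voom in either direction (also none adjusted over the list alone; camera adjusted p = 0.277), with 4 at an unadjusted p under 0.05 and 1 called by DESeq2. Fzd1 (0.55, edgeR adjusted p = 0.0941) and Apc (-0.44, edgeR adjusted p = 0.109) had the smallest p-values among them, and Fzd1 was called higher in 4 of 17 alternative fits. Notum shares its locus with the antisense transcript Notumos, which is outside the naming rule, and with no strand setting stated their reads cannot be told apart.

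Targets of p53 were also higher in part. Of 26 tested, 12 were higher and none was lower by edgeR, DESeq2 or limma-voom (15 higher and 0 lower at an unadjusted p under 0.05, and 15 higher adjusted over the list alone). The list had a median of 0.56 and camera adjusted p = 2.19e-10 (adjusted p = 0.145 with an estimated correlation). Cdkn1a rose from 3.85 ± 1.26 to 70.3 ± 8.03 CPM (log2 fold change 4.19, SE 0.22, edgeR adjusted p = 5.06e-06). Ccng1, the cyclin G1 gene, rose from 64.9 ± 1.47 to 174 ± 17.5 CPM, Eda2r, a receptor of the TNF family, from 9.69 ± 1.71 to 34.9 ± 6.07 CPM and Psrc1 from 37.7 ± 4.69 to 91.3 ± 8.01 CPM. Of other p53 list members known from cell death, some were called and some were not, and they were not tested as a group. Called higher were Bax (0.91, edgeR adjusted p = 0.0138), Bbc3, which encodes Puma (1.08, edgeR adjusted p = 0.0133), Perp (1.54, edgeR adjusted p = 0.0101) and Aen (0.69, edgeR adjusted p = 0.0259). Each of these 4 lost its call in 2 to 5 of 17 alternative fits. Pmaip1 (0.84, edgeR adjusted p = 0.423), Tnfrsf10b (0.55, edgeR adjusted p = 0.183), Ei24 (0.18, edgeR adjusted p = 0.511) and Fas (-0.41, edgeR adjusted p = 0.692) were not called. With 1 library left out, the value of Pmaip1 ran from 0.08 to 1.23. All 8 are outside the naming rule and were chosen after their values were seen. The choice left out other called members of the list, so its balance of called and uncalled genes is not that of the list. On a separate list of 18 apoptosis effectors and regulators, which holds none of the 8, 1 gene rose and none fell by edgeR, DESeq2 or limma-voom (4 higher and 2 lower at an unadjusted p under 0.05, and 1 higher adjusted over the list alone; camera adjusted p = 0.549). That gene was Bcl2l11, which encodes the pro-apoptotic protein Bim, at 80.7 ± 29.9 CPM in cKO and 38.5 ± 4.23 CPM in WT (log2 fold change 1.07, SE 0.222, edgeR adjusted p = 0.0238). Its call was lost in 6 of the 17 alternative fits, with adjusted p up to 0.106.

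Most Sertoli cell markers fell. Of 27 fetal Sertoli cell markers tested, 22 were lower in cKO by edgeR, 24 by DESeq2 and 23 by limma-voom, and none was higher by any of them (0 higher and 24 lower at an unadjusted p under 0.05, and 24 lower adjusted over the list alone). Their median log2 fold change was -1.43, with camera adjusted p = 2.9e-21 (adjusted p = 0.195 with an estimated correlation). Hsd17b3 went from 131 ± 16.7 to 13.2 ± 3.81 CPM (log2 fold change -3.31, SE 0.206, edgeR adjusted p = 1.35e-05), Sox8, a relative of Sox9, from 91.2 ± 0.913 to 13.3 ± 3.59 CPM, Defb19 from 77.2 ± 4.77 to 13.1 ± 1.49 CPM and Cst9 from 79.0 ± 7.53 to 15.3 ± 3.81 CPM. The most abundant members also fell. Amh, the hormone that regresses the Müllerian duct, went from 897 ± 239 to 168 ± 100 CPM (-2.41, SE 0.365, edgeR adjusted p = 0.00381) and Clu from 919 ± 177 to 507 ± 43.2 CPM (-0.86, SE 0.158, edgeR adjusted p = 0.0124). The 5 markers not called by edgeR fall outside the naming rule and are named after their values were seen: Wt1 (0.23), Nr5a1 (0.05), Fgf9 (0.29), Gata4 (-0.48, edgeR adjusted p = 0.0579) and Cyp26b1 (-0.93, edgeR adjusted p = 0.0864). Of these, Gata4 was called lower in 6 and Cyp26b1 in 4 of 17 alternative fits. Sox9, the factor that directs Sertoli cell fate, was also chosen after its values were seen and was lower at 59.9 ± 16.4 against 122 ± 10.9 CPM (log2 fold change -1.03, SE 0.184, edgeR adjusted p = 0.0106). Its call was lost in 2 of 17 alternative fits, at adjusted p up to 0.0671. Among 17 junction and barrier genes of Sertoli cells, 4 were lower and none was higher by edgeR and by limma-voom, and 5 were lower and 1 higher by DESeq2 (5 lower and 1 higher at an unadjusted p under 0.05, and as many adjusted over the list alone). Camera gave this list an adjusted p of 0.0529 and called it in 3 of 6 fits with 1 library left out. Lower by edgeR were Espn, an actin bundler (-1.25), Gja1, the connexin 43 gene (-1.26), F11r (-0.68) and Jam2 (-1.24), while Itgb1 stood at 530 ± 35.6 and 526 ± 43.5 CPM.

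**Figure D2:**
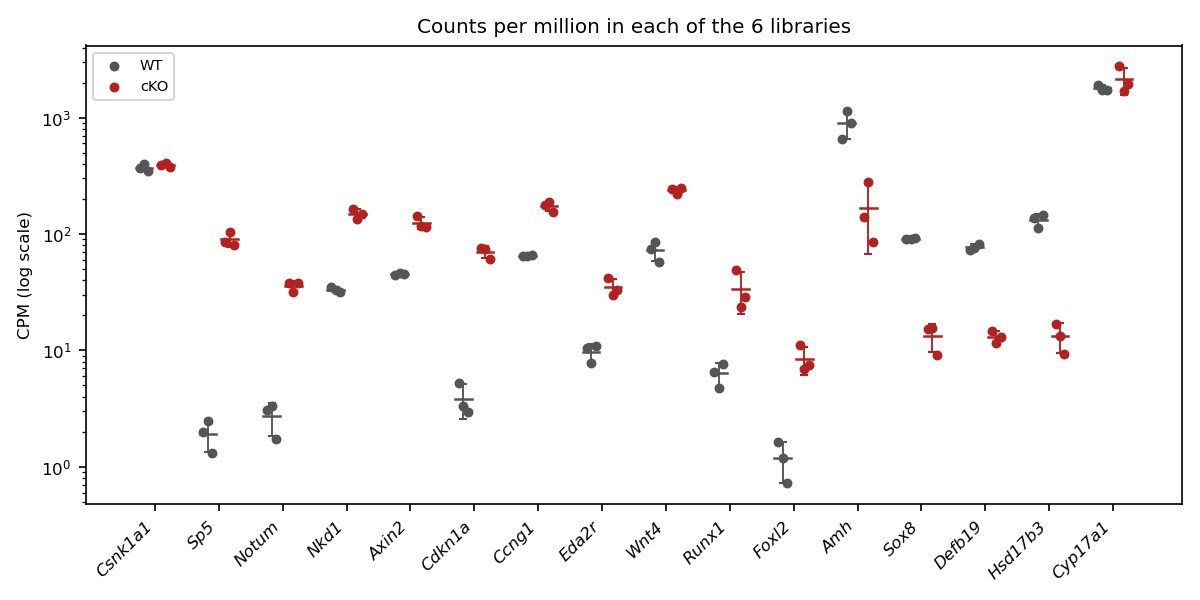
CPM on a log axis of 16 genes (horizontal axis) in the 3 WT (gray) and 3 cKO (red) libraries. Points are libraries, horizontal bars are means and vertical bars are 1 SD. The cKO values of Sp5, Cdkn1a and Wnt4 lie above all WT values, those of Amh, Sox8, Defb19 and Hsd17b3 below, and those of Csnk1a1 and Cyp17a1 overlap with WT.

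Genes listed as markers of pregranulosa cells, the supporting cells of the fetal ovary, and of the ovarian pathway went both ways. Of 18 tested, 4 were higher, 2 lower and 12 not called by edgeR, and DESeq2 and limma-voom also called 4 higher and 2 lower. At an unadjusted p under 0.05, 6 were higher and 2 lower, against 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.13). Wnt4, a signal needed for ovary formation, rose from 72.8 ± 14.4 to 238 ± 15.6 CPM (log2 fold change 1.71, SE 0.153, edgeR adjusted p = 0.00015). Runx1 rose from 6.33 ± 1.44 to 33.8 ± 13.3 CPM (2.41, SE 0.283, edgeR adjusted p = 0.000754), and Foxl2, a transcription factor that maintains granulosa cells, from 1.18 ± 0.451 to 8.46 ± 2.27 CPM (2.84, SE 0.365, edgeR adjusted p = 0.00141). Nr0b1, the remaining higher member, is outside the naming rule and rose by 1.16 on the log2 scale. Hsd17b1, which makes estradiol from estrone, fell by 1.96 and Fshr by 3.12 on the log2 scale, and Kitl was not called (0.27, edgeR adjusted p = 0.388). In WT testes Hsd17b1 stood at 102 ± 27.4 CPM and Fshr at 12.9 ± 3.30 CPM. Whole-testis counts do not tell whether the falls of Hsd17b1 and Fshr belong to an ovarian pathway or to cells of the normal testis. With 1 library left out, the log2 fold change of Fshr ran from -3.98 to -2.70.

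The remaining cell types of the organ showed few called genes. Among 16 genes of fetal Leydig cells and steroid synthesis, Fdx1 and Por, electron donors of steroidogenic enzymes, rose by 0.85 and 0.59 on the log2 scale and none fell by edgeR. The calls of Fdx1 and Por were lost in 4 and 7 of 17 alternative fits. DESeq2 called 5 higher and 1 lower and limma-voom 3 higher and 0 lower (6 higher and 1 lower at an unadjusted p under 0.05, and 5 higher and 1 lower adjusted over the list alone). The list median was 0.40 with camera adjusted p = 0.00198 (adjusted p = 0.42 with an estimated correlation). The abundant enzymes Cyp11a1 (1588 ± 106 and 1052 ± 165 CPM, edgeR adjusted p = 0.0636) and Cyp17a1 (2137 ± 557 and 1792 ± 110 CPM, edgeR adjusted p = 0.553) were not called by edgeR, and Cyp11a1 was called higher in 4 of 17 alternative fits. Of 18 interstitial and stromal progenitor markers 1 was called higher by edgeR and by limma-voom and 5 by DESeq2, against 9 higher adjusted over the list alone. Their median was 0.36, with camera adjusted p = 9.11e-05 (adjusted p = 0.425 with an estimated correlation). The most abundant members Col3a1 and Dlk1 stood at 0.56 and 0.67 (edgeR adjusted p = 0.25 and 0.106) and were called higher in 2 and 4 of 17 alternative fits. Of 13 genes of peritubular myoid cells and smooth muscle, Des, an intermediate filament gene, rose by 0.72 and Ptch1, the Hedgehog receptor, fell by 0.87 on the log2 scale (2 higher and 1 lower by DESeq2, and 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.465), and Acta2 was not called (-0.19). Kdr, a receptor of the growth factor VEGF, was the 1 called by edgeR among 16 endothelial markers (higher by 0.66; 1 by limma-voom, 2 by DESeq2 and 1 adjusted over the list alone; camera adjusted p = 0.149). None of 20 macrophage and leukocyte markers was called by edgeR, DESeq2 or limma-voom (2 at an unadjusted p under 0.05 and none adjusted over the list alone; camera adjusted p = 0.507). Of 10 erythroid genes Hba-a1, an alpha globin whose near-identical copy was not matched, rose from 38.1 ± 15.4 to 113 ± 57.1 CPM, and 9 of the 10 had a positive fold change (1 higher adjusted over the list alone; list median 0.69; camera adjusted p = 0.147). Emx2 was the 1 called by edgeR among 15 genes of mesonephros and ducts (higher by 1.06; 1 by limma-voom, 2 by DESeq2 and 2 adjusted over the list alone; camera adjusted p = 0.237). Among 6 adrenal markers Pnmt, which makes adrenaline, fell by 4.16 on the log2 scale (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.701; median 0.09 and mean -0.33), and the adrenal marker Akr1b7 stood at -0.18 (edgeR adjusted p = 0.86).

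Few germ cell transcripts were called. Of 21 markers of male germ cells, Mov10l1, a helicase of the piRNA pathway, fell from 168 ± 47.6 to 97.0 ± 6.73 CPM (log2 fold change -0.79, SE 0.186, edgeR adjusted p = 0.0434) and the other 20 were not called by edgeR. DESeq2 called 2 lower, limma-voom called none, and none was higher by any of these tools (0 higher and 4 lower at an unadjusted p under 0.05, and 1 lower adjusted over the list alone). The call of Mov10l1 was lost in 7 of 17 alternative fits. The list median was -0.28 with camera adjusted p = 0.0346 (adjusted p = 0.674 with an estimated correlation), and 5 of the 21 fold changes were positive. The call of this list was lost in 6 of 12 alternatives, at adjusted p up to 0.745. Piwil4 (-0.60, edgeR adjusted p = 0.139) and the abundant Piwil2 (-0.38, edgeR adjusted p = 0.371) were not called by edgeR, and Piwil4 was called lower in 3 of 17 alternative fits. None of 18 meiosis genes was called by edgeR or limma-voom (2 at an unadjusted p under 0.05, 1 by DESeq2 and none adjusted over the list alone; camera adjusted p = 0.685). The largest value was that of Stra8, which germ cells switch on before meiosis, with 12.9 ± 7.63 CPM in cKO and 2.49 ± 2.43 CPM in WT (log2 fold change 2.37, SE 0.623, edgeR adjusted p = 0.0722). WT library 1 held 5.29 CPM of it against 0.931 and 1.26 CPM in the other WT libraries. With 1 library left out its log2 fold change ran from 1.90 to 3.55, the highest without WT library 1, and it was called higher in 3 of 17 alternative fits. Of 21 proliferation and mitosis genes none was called by edgeR or limma-voom and 2 were called lower by DESeq2 (7 at an unadjusted p under 0.05 and 3 lower adjusted over the list alone), with Cenpe at -0.51 (edgeR adjusted p = 0.0609) and Plk1 at -0.57 (edgeR adjusted p = 0.0692), called lower in 5 and 3 of 17 alternative fits. That list's median was -0.13 with camera adjusted p = 0.0228 (adjusted p = 0.592 with an estimated correlation), and its call was lost in 5 of 12 alternatives.

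Genes of retinoic acid metabolism and response rose in part, with 7 of 13 fold changes positive. Of 13 tested, 4 were higher and none was lower by edgeR and by limma-voom, and 5 were higher and 2 lower by DESeq2 (7 higher and 2 lower at an unadjusted p under 0.05, and as many adjusted over the list alone). Their median was 0.46, with camera adjusted p = 0.0172 (adjusted p = 0.287 with an estimated correlation, and 0.06 with genes of a mean of at least 1 CPM, where the call was also lost). Higher by edgeR was, among others, Stra6, the retinol importer, from 39.0 ± 4.23 to 124 ± 32.3 CPM (log2 fold change 1.67, SE 0.185, edgeR adjusted p = 0.000525). Aldh1a3 and Rdh10, enzymes of retinoic acid synthesis, were also higher, at 1.18 and 0.73. Among 22 TGF-β, activin and BMP signalling genes, Tgfb2 (0.88), Id2 (1.46) and Id1 (0.82) were higher, and Inhbb (-1.43), an inhibin and activin subunit that was also on the Sertoli list, and Smad7 (-0.64), outside the naming rule, were lower (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.321). Of 25 genes of basement membrane and extracellular matrix, Nid2 (0.65), Lum (0.71) and Eln (0.81) were higher and none was lower by edgeR (3 higher and 0 lower also by DESeq2, by limma-voom and adjusted over the list alone, and 6 higher and 0 lower at an unadjusted p under 0.05). Camera gave this list an adjusted p of 0.113 and called it in 3 of 6 fits with 1 library left out. Its most abundant member, Col1a1, was not called by edgeR (0.70, edgeR adjusted p = 0.274) and was called higher in 3 of 17 alternative fits. Hk2, a hexokinase, was the 1 called by edgeR and by limma-voom among 16 glycolysis genes (lower, -0.61; 1 higher and 1 lower by DESeq2, and 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.832). Egr1 was the 1 called by edgeR among 17 immediate-early genes (lower, -0.98; 2 higher and 1 lower by DESeq2, 1 higher and 1 lower by limma-voom, and 3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.135). None of 19 cholesterol synthesis genes (camera adjusted p = 0.0529) and none of 14 interferon-response genes (camera adjusted p = 0.182) was called by edgeR, DESeq2 or limma-voom, with 2 and 0 of them at an unadjusted p under 0.05 and none adjusted over the list alone. Camera called the cholesterol list with a replicate block and in 3 of 6 fits with 1 library left out.

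**Figure D3:**
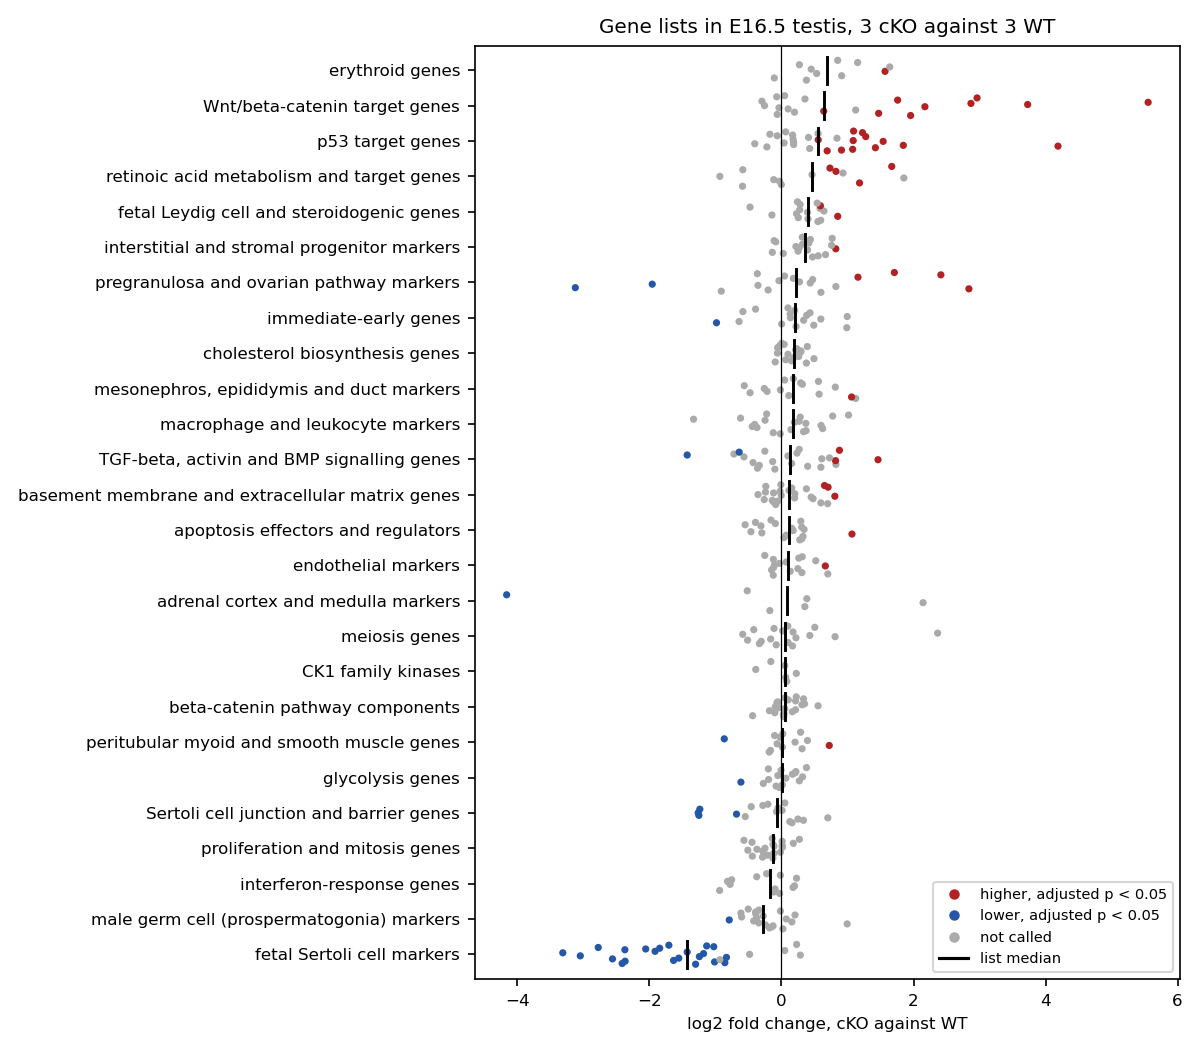
Log2 fold change of cKO against WT (horizontal axis) for every tested member of the 26 gene lists (vertical axis), ordered by list median (black bars). Red and blue points were called higher and lower by edgeR over all genes and gray points were not called. The median of the fetal Sertoli markers lies at -1.43, and those of the Wnt/β-catenin and p53 targets at 0.64 and 0.56.

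Libraries differed in ways that the groups do not fully account for. Pearson correlations of log2 CPM were 0.980 to 0.981 between WT libraries and 0.959 to 0.975 between cKO libraries, and the first principal component (39.6% of the variance) set cKO library 2 farthest from the WT libraries, at -69.1 against 17.1 to 42.6. Fewer genes had at least 1 count in cKO libraries (25183, 22865 and 26028) than in WT libraries (26605, 26453 and 27358). Of 71 called genes given a value, 44 kept their call in all 17 alternative fits and 27 lost it in at least 1, none of them with a log2 fold change beyond 1.57 in size. Of the 26 lists, camera called 8, of which 5 were higher and 3 lower. With an estimated correlation it called 0 (4 at an unadjusted p under 0.05), and fry called 4. Fry tests whether a list's genes move one way on balance without comparing them with other genes.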

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

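No called value changed direction in any alternative, and the 615 calls held 0 genes whose sign turned. Csnk1a1 stayed uncalled, at 0.04 to 0.14 over all alternatives, and the scalings moved the median of all genes by less than 0.1. For genes higher and lower in cKO (276 and 339), the DESeq2 Wald test gave 499 and 538, no low-count filter 613 and 651, limma-trend on log2(FPKM + 0.1) 149 and 223, and limma-trend on log2(FPKM + 1) 156 and 241. That last alternative gave 207 genes with a 2-fold change against 328. Leaving out 1 library gave 105 to 342 higher, 167 to 399 lower, 221 to 369 with a 2-fold change, and 7 to 10 lists. The cause was not tested, beyond the fewer libraries or larger gene set of an alternative. Of the 62 called genes of the naming rule, 40 to 62 kept their call over all alternatives and 40 to 59 with 1 library left out (40 without WT library 3, where 268 of the 615 calls were shared). Of 103 genes given a value besides Csnk1a1, 71 were called, and 44 of these held in all 17 alternatives. The other 27 lost their call in at least 1. Hk2, Lum, Mov10l1, Por and Smad7 lost it in 7, and Bcl2l11, Des, Egr1 and Eln in 6. Aen, Aldh1a3, Clu, Hba-a1 and Rdh10 lost it in 5, and Fdx1, Id1, Id2, Jam2 and Nid2 in 4. Bax, F11r, Kdr and Ptch1 lost it in 3, Bbc3, Perp and Sox9 in 2 and Emx2 in 1. Of the 32 not called, 11 were called in at least 1 of the 17: Gata4 in 6, Cenpe in 5, Cyp11a1, Cyp26b1, Dlk1 and Fzd1 in 4, Col1a1, Piwil4, Plk1 and Stra8 in 3 and Col3a1 in 2. List calls fell from 8 to 0 with an estimated correlation and to 4 with fry (Wnt/β-catenin targets, p53 targets, Sertoli markers, retinoic acid genes). The size of the correlation does not account for all of the fall to 0. The estimated correlation of the retinoic acid list was 0.00898, below the preset 0.01. Its unadjusted camera p still went from 0.00396 to 0.0442. Camera on genes with a mean of at least 1 CPM called 7, without the retinoic acid genes (adjusted p = 0.06). Whether equal replicate numbers paired the libraries stayed open. Deviations correlated at 0.017, 0.184 and 0.032 in pairs of equal number and at -0.173 to 0.157 in the others. Libraries 2 and 3 of cKO correlated best with the WT library of equal number, and cKO library 1 with WT library 3. A replicate block gave 324 higher, 372 lower, 336 with a 2-fold change and 8 lists, of which 7 were shared: male germ cell markers lost their call and cholesterol synthesis genes gained one. Of the 6 fits with 1 library left out, 3 each called the lists of cholesterol synthesis, of Sertoli junctions and of basement membrane, and 1 each those of erythroid genes and of pregranulosa markers, which the main fit did not call.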

Other observations

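Tests of the Sertoli share, of a wrong label, of the reads of Csnk1a1, of the splits by direction and size, and of gene detection were chosen only after the results were seen. The genes of secreted signals in this paragraph, other than Wnt4, Wnt7b and Kitl, and also Gli1, Mdm2 and Ctnnb1, fall outside the naming rule and were chosen after their values were seen, so they describe single genes and no group. Gdnf, the growth factor that maintains spermatogonial stem cells, was 3.49-fold lower (39.2 ± 7.78 to 11.2 ± 2.1 CPM, edgeR adjusted p = 0.00048), Pdgfa 2.56-fold lower (97.2 ± 4.95 to 38.0 ± 6.37 CPM, edgeR adjusted p = 0.000362) and Dhh, the Hedgehog ligand of the fetal testis, 2.94-fold lower (137 ± 13.1 to 46.6 ± 13.9 CPM, edgeR adjusted p = 0.000966). Of the Hedgehog response genes, Ptch1 was lower (log2 fold change -0.87) and Gli1 was not called (0.03, SE 0.136, edgeR adjusted p = 0.947). Other signal genes were not called by edgeR, such as Fgf9 (0.29, edgeR adjusted p = 0.651) and Kitl (0.27, edgeR adjusted p = 0.388). Of Wnt ligand genes, Wnt4 and Wnt7b (9.11-fold) were higher, Wnt5a was not called (0.32, edgeR adjusted p = 0.333) and Wnt11 was 4.21-fold higher (7.97 ± 0.619 to 33.6 ± 1.89 CPM, edgeR adjusted p = 7.27e-05). Among well known members of the pathways above, Mdm2 (0.18, SE 0.158, edgeR adjusted p = 0.631) and Ctnnb1, the β-catenin gene (0.21, SE 0.128, edgeR adjusted p = 0.47), were not called.

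Sertoli markers were lower in cKO, and a smaller number of Sertoli cells is a possible explanation. If a lower share of these cells were the whole of it, transcripts taken to come from Sertoli cells alone would fall by a common amount. Over 9 such transcripts (Amh, Sox8, Cst9, Hsd17b3, Defb19 and, outside the naming rule, Sox9, Dhh, Ptgds and Aard) the log2 fold changes ran from -3.31 for Hsd17b3 to -1.03 for Sox9, with Cochran's Q = 112.5 on 8 degrees of freedom (95th percentile of chi-square 15.5). This test was chosen after the results were seen. Q also takes the errors of the 9 transcripts as independent, though all come from the same libraries. Within these limits, a lower share alone is argued against as far as these transcripts have no other source. Scaling is argued against only for the 3 other scalings, under which the list median was at most -1.42. These scalings hardly moved the median of all genes (-0.0255 to 0.00611), so a larger scaling error was not tested. A changed state of the cells, with or without a loss of cells, stays open and was not tested: interstitial and Leydig lists were higher by camera (medians 0.36 and 0.40, 15 of 18 and 14 of 16 positive; adjusted p = 0.425 and 0.42 with an estimated correlation), as a lower Sertoli share would give, beside male germ cell markers at -0.28 (5 of 21 positive) and endothelial and myoid lists, not called, at 0.10 and 0.01.

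Csnk1a1 was not lower in the libraries labelled cKO. A wrong label on 1 library is argued against, because 0 libraries had a mean of the Sertoli, Wnt target or p53 target lists inside the range of the other group, although an exchange of all labels between the groups would leave this value at 0. Reads of Csnk1a1 from cells other than Sertoli cells, or from exons left in the deleted gene, may hide the deletion. The 95% interval allows a fall of up to 11.5% in the whole testis, and this cannot be told apart from no loss because the share of Csnk1a1 reads that come from Sertoli cells and the deleted exons are not known here.

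Fewer genes were detected in cKO libraries. Depth is argued against: with all libraries thinned to 15092619 counts, cKO libraries still held 25183, 22845 and 25806 genes and the lowest WT library held 610 genes more than the highest cKO library. Uneven amplification of the same RNA could drop rare genes at random, which leaves their summed counts alike. The summed CPM of 6999 genes with a mean of 0.01 to 0.1 CPM was 232, 159 and 271 in cKO libraries and 331, 303 and 392 in WT libraries. Every cKO library thus lay below the WT range, which uneven amplification alone was not predicted to give. The gap of 32.2 between the groups was still smaller than 1 SD of the WT libraries. Uneven amplification therefore cannot be told apart from a difference between the genotypes. Of the 615 called genes, 13 had a mean under 1 CPM.

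The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 615 genes (276 higher, 339 lower, 328 with a 2-fold change) and the highest of the other splits called 0, so 1 of the 10 splits gave as many. Each of the other splits put cKO and WT libraries on both sides. Differences between the genotypes then add to the spread within a side, so 0 calls there is not a null count. By edgeR these other splits held 230 to 1756 genes at an unadjusted p under 0.05, against 2900. The real split called 8 lists by camera and the highest other split also 8, so 2 of the 10 splits gave as many.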
